A study of Homo sapiens with 30 samples.

How the data were processed

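RNA-seq was done on VCaP cells given a control siRNA or an siRNA against RB1 (20 nM, 2 days), on C4-2-tet-shRB cells with or without doxycycline (0.05 µg/ml) and with DHT (10 nM, 24 h) or GSK2879552 (10 µM, 24 h), and on LNCaP cells with GSK2879552 (1 µM, 2 days). Per the labels, the VCaP medium held 10% serum, whereas the names of the VCaP libraries refer to charcoal-stripped serum, and which applied was not settled. The C4-2 and LNCaP media held charcoal-stripped serum per the labels, with fetal bovine serum besides in the DHT experiment. Differences of androgen-regulated genes between lines or experiments are thus not separated from the medium. Total RNA kits were used for the DHT and LNCaP tables and mRNA kits for the other two, per the labels. Per the submitters' processing notes, reads went through FastQC 0.11.9, STAR 2.7.2 and featureCounts 1.6.4 with the hg19 (GRCh37) genome. Strand setting, annotation version and treatment of reads with several alignments were not given in the sources used here. The values deposited by the authors were counts, as raw reads per Ensembl gene, with no normalization. All 30 columns were mapped to a sample (0 were not).

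The series description states that all samples contain replicates. In the DHT and LNCaP tables, per the labels, both columns of a group carry the same library name and index and differ in the lane. A chi-square ratio over genes with at least 10 counts in the pair, with a limit of 1.5, was set to decide whether they differ by counting error alone. It was 0.983 to 1.01 in the DHT table and 0.994 to 0.996 in the LNCaP table, so these columns were summed as lanes of 1 library. Columns of the other tables carry separate library names and entered as replicates. Their ratio was 1.61 to 7.88 in the C4-2 table with GSK2879552. The highest was that of the pair given the inhibitor alone, and the other groups had 1.61 to 3.56. In the VCaP table the ratio was 1.13 to 1.39, and replicates there differ by little more than counting error. These VCaP values are also under 1.5, but the limit was applied only to columns that share a library name. The rule and all choices not named below as later ones were fixed before the data were examined.

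Each table was fitted separately with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the SE was the log2 fold change divided by the square root of F. VCaP groups were compared directly. The 4 C4-2 groups with GSK2879552 were fitted together, which gave the effect of doxycycline without the inhibitor, the effect of the inhibitor without and with doxycycline, and the difference between these effects. The 6 C4-2 libraries with DHT were fitted with an additive model of doxycycline level and DHT, which leaves 2 residual degrees of freedom and takes the DHT response as equal at all levels. The prior degrees of freedom were 76.7 for VCaP, 12.9 for C4-2 with GSK2879552 and 24.4 for C4-2 with DHT, and the biological coefficients of variation were 2.27%, 5.79% and 5.00%. Such a low variation between replicates bounds the spread of these samples, not of independent experiments.

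For LNCaP cells and for DHT at each doxycycline level, TMM-scaled ratios of 1 library to 1 library were described for genes with at least 100 counts in the pair, with a fold of 2 as the limit. Their 95% intervals are exact binomial (Clopper-Pearson) intervals of the counts. A fold against 0 counts used a floor of 3 counts over the group. Log2 CPM values, and so the 2-fold limit and the order of genes, used a prior count of 2, while ratios printed for single LNCaP genes are those of the scaled counts without it. The 24 gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 5 measured members, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation the test has only the residual degrees of freedom of the fit. These were 4 in the VCaP table and the C4-2 table with GSK2879552, and 2 in that with DHT, where its power is low. Without a test, a list median was placed among those of 10000 random lists drawn from 20 expression bins. Such a percentile takes account neither of correlation between the genes of a list nor of the spread between libraries. Overlaps of called genes used a two-sided Fisher's exact test.

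The genes named in every comparison were RB1, KDM1A, KLK3 and E2F1. Some genes that the rule named are not reported here. Further named genes were the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1. Each list described added up to 2 members with the smallest p in each direction, and each overlap the 5 leading genes per direction. Genes named in 1 comparison were followed in others. Genes followed in the closing section (ODC1, LAP3, PPIC, LMNB1, STAMBP and LINC00472) were chosen after their values were seen.

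Depth was 4311455 to 7107036 counted reads per VCaP library, 14515932 to 22326960 in the C4-2 table with GSK2879552, 14898454 to 16856486 per library in that with DHT and 13085157 and 14036346 in the LNCaP libraries. Tested on simulated data with the fitted means and trended dispersions and 200 changed genes per comparison, the tests recovered 68.7% to 94.0% of 2-fold changes, with 2.17% to 6.45% false calls. Of 1.5-fold changes they recovered 52.2% to 76.1%. A response as broad as that called with DHT was not simulated. Each simulated gene had the dispersion of the trend, and no library was made discordant, so these rates may be better than those in the data. Alternatives were DESeq2 1.42.0 with its Wald test, median-of-ratios scaling, no count filter, leaving out each library, a replicate block, fits of the compared groups alone, lanes as replicates, other count minimums and scaling by total counts. Added after seeing the data were thinning of the VCaP libraries to the shallowest, crossed replicate numbers, removal of the genes of the mitochondrial genome and a joint fit of both C4-2 tables. The tally of genes called in C4-2 cells over the LNCaP libraries was also added then, as was the test of the DHT response with and without doxycycline. Genomic positions were not used here, since the reference at hand has another genome build than the counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.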

Results

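RNA was sequenced from 3 human prostate cancer cell lines in 4 count tables that held 30 columns from 22 libraries in 14 groups. VCaP cells had received a control siRNA or an siRNA against RB1, the retinoblastoma tumour suppressor that restrains E2F transcription factors (3 libraries each, 4311455 to 7107036 counted reads per library). C4-2-tet-shRB cells carry a doxycycline-inducible short hairpin RNA against RB1. In 1 table these cells were kept without or with doxycycline and given DMSO or GSK2879552, an inhibitor of the histone demethylase LSD1 (KDM1A), with 2 libraries per group and 14515932 to 22326960 reads each. In another they had 0, 3 or 30 days of doxycycline and vehicle or the androgen dihydrotestosterone (DHT), with 1 library per group read in 2 lanes and 14898454 to 16856486 reads per library. Neither table held doxycycline-treated cells with a control hairpin. Effects of RB1 loss are thus not separated from those of doxycycline or hairpin induction in C4-2 cells. In VCaP cells effects of RB1 loss are not separated from other effects of the RB1 siRNA. LNCaP cells were given vehicle or GSK2879552, again with 1 library per group (14036346 and 13085157 reads). Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nothing in the labels states that replicates were separate cultures and not technical repeats, so the p-values measure only the spread between these samples. In VCaP cells this spread was little above counting error (chi-square ratio 1.13 to 1.39 between replicates).

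Depletion of RB1 in VCaP cells asked which genes depend on this tumour suppressor without a change of hormone. RB1 stood at 56.5, 60.0 and 63.9 CPM (counts scaled to library size) in the 3 control siRNA libraries and at 5.35, 6.74 and 7.41 CPM in the 3 RB1 siRNA libraries. It fell by 3.22 ± 0.12 on the log2 scale (adjusted p = 4.55e-39, n = 3 per group in edgeR). E2F1, which drives entry into S phase, rose by 0.41 ± 0.06 (adjusted p = 1.06e-07). KLK3, an androgen-induced gene that encodes prostate-specific antigen, rose by 0.38 ± 0.04 (adjusted p = 3.32e-11). KDM1A, the gene of LSD1, had no call (log2 0.05 ± 0.04, adjusted p = 0.589). Of 18 members and partners of the LSD1-CoREST complex 1 rose (camera adjusted p = 0.397).

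**Figure D1:**
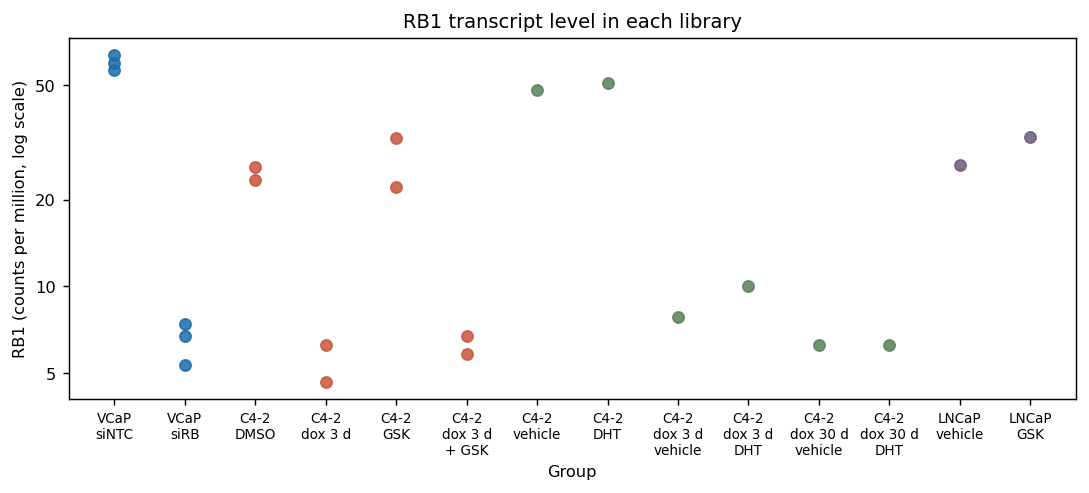
RB1 in CPM (log axis) in each of the 22 libraries, by group; each point is 1 library. The RB1 siRNA libraries lie between 5.35 and 7.41 CPM and the control siRNA libraries between 56.5 and 63.9 CPM, and each doxycycline group lies below its control without doxycycline.

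Genes of DNA replication rose after RB1 depletion in VCaP cells, and genes of mitosis fell. Of the 55 E2F-driven G1/S genes 23 rose (34 adjusted over the list alone) with a list median of 0.24. Among them were the replicative helicase subunit MCM2 (log2 0.34 ± 0.04) and thymidine kinase TK1 (log2 0.39 ± 0.05). camera gave the list an adjusted p of 3.99e-21, and 0.00824 with an estimated correlation. Of the 46 G2/M genes 10 fell (18 adjusted over the list alone), including the mitotic kinase AURKA (log2 -0.49 ± 0.07) and the kinesin KIF20A (log2 -0.45 ± 0.06), while MYBL2 rose (log2 0.33 ± 0.05). The G2/M median was -0.14 (camera adjusted p = 2.7e-08, and 0.0433 with an estimated correlation). BRCA1 was the 1 of 22 homologous recombination genes that rose (2 adjusted over the list alone; log2 0.29 ± 0.07).

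Interferon-stimulated genes also rose in VCaP cells. Of 35 measured members 24 rose (25 adjusted over the list alone), with IFI27 at 1.22 ± 0.07 (adjusted p = 1.27e-25) and IFI6 at 0.42 ± 0.03. Their median was 0.30 (camera adjusted p = 3.07e-21, and 0.00793 with an estimated correlation). In C4-2 cells with doxycycline and DMSO, 2 were higher and 6 lower at an unadjusted p under 0.05 in edgeR. IFI6 stood there at -0.36 ± 0.13 (adjusted p = 0.0951). In the DHT experiment 3 were higher and 2 lower after 3 days, and 6 higher and 1 lower after 30 days. In VCaP cells, genes of the ATF4 integrated stress response rose in 16 of 29 cases (21 adjusted over the list alone, 7 called by DESeq2). Examples were the phosphatase subunit PPP1R15A (log2 0.61 ± 0.07) and the amino acid transporter chain SLC3A2 (log2 0.42 ± 0.05), and the list had a camera adjusted p = 6.52e-12, and 0.0099 with an estimated correlation. Hypoxia and glycolysis genes rose in 11 of 22 cases (16 adjusted over the list alone). They included the collagen prolyl hydroxylase P4HA1 (log2 0.67 ± 0.08) and the angiogenic factor VEGFA (log2 0.55 ± 0.06; camera adjusted p = 8.62e-13, and 0.025 with an estimated correlation).

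Androgen-regulated genes and mitochondrial transcripts also moved in VCaP cells, but their camera calls were lost with an estimated correlation. Of 40 androgen-induced genes 12 rose (14 up and 5 down adjusted over the list alone), including KLK3 and the stress-regulated NDRG1 (log2 0.20 ± 0.03; adjusted p = 0.0697 with an estimated correlation). Of 14 androgen-repressed genes 6 fell (7 adjusted over the list alone), including the opioid receptor OPRK1 (log2 -0.34 ± 0.05; adjusted p = 0.0711 with an estimated correlation). All 13 protein genes of the mitochondrial genome fell, with MT-CYB at -0.34 ± 0.03 and MT-CO3 at -0.31 ± 0.03 and a median of -0.24 (adjusted p = 0.0711 with an estimated correlation). Of 18 neuroendocrine markers 3 fell, among them the adhesion molecule NCAM1 (log2 -0.92 ± 0.17) and PEG10 (log2 -0.36 ± 0.03), and 1 rose (adjusted p = 0.135 with an estimated correlation). The lipid synthesis regulator SREBF1 (log2 -0.47 ± 0.05) and the desaturase SCD (log2 -0.26 ± 0.04) fell.

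In all, 417 genes rose and 373 fell of 14066 tested in VCaP cells, of which 12 rose and 7 fell at least 2-fold. The largest rises were those of the cytokine receptor TNFRSF12A (log2 1.53 ± 0.37), the ephrin EFNA4 (log2 1.51 ± 0.42), HCP5 (log2 1.41 ± 0.18), GHRHR (log2 1.29 ± 0.41), ADIPOR1P2 (log2 1.25 ± 0.40) and IFI27. After RB1, the largest falls were those of ASPG (log2 -1.34 ± 0.38), C3orf72 (log2 -1.24 ± 0.32), RPL23P8 (log2 -1.13 ± 0.31), the actin regulator CFL2 (log2 -1.04 ± 0.10) and HLA-DMA (log2 -1.03 ± 0.30). The pseudogenes ADIPOR1P2 and RPL23P8 and the HLA genes share sequence with relatives, so their values are uncertain. DESeq2 called 171 genes up and 170 down, and edgeR called 524 genes without control siRNA replicate 2 and 515 without control siRNA replicate 3. Calls that ended when 1 library was left out were those of TNFRSF12A without control siRNA replicate 3 (1.35), EFNA4 without control siRNA replicate 3 (1.18), and C3orf72 without control siRNA replicate 3 (-1.08). ADIPOR1P2 lost its call without control siRNA replicate 1 (0.89), 2 (1.59) or 3 (1.38). GHRHR lost it without control siRNA replicate 1 (1.09), 2 (1.604) or 3 (1.21) or RB1 siRNA replicate 1 (1.35), 2 (1.27) or 3 (1.25). ASPG lost it without control siRNA replicate 2 (-1.38) or 3 (-1.10) or RB1 siRNA replicate 1 (-1.28) or 2 (-1.35). RPL23P8 lost it without control siRNA replicate 1 (-1.07) or 2 (-1.01) or RB1 siRNA replicate 2 (-0.88), and HLA-DMA without control siRNA replicate 1 (-1.04) or 3 (-0.85) or RB1 siRNA replicate 1 (-0.95) or 3 (-0.85).

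Doxycycline in C4-2-tet-shRB cells without GSK2879552 asked a related question in castration-resistant cells after 3 days of RB1 knockdown. These cells were in charcoal-stripped serum per the labels, so androgen-regulated genes such as KLK3 may not be comparable with VCaP cells. RB1 stood at 23.4 and 26.1 CPM in the 2 DMSO libraries and at 4.64 and 6.24 CPM with doxycycline. It fell by 2.18 ± 0.18 on the log2 scale (adjusted p = 3.43e-06, n = 2 per group in edgeR). E2F1 rose by 0.42 ± 0.08 (adjusted p = 0.00343) and KLK3 fell (log2 -0.29 ± 0.05, adjusted p = 0.00219). The E2F1 call ended without DMSO replicate 1 (0.44) or 2 (0.40) or doxycycline replicate 1 (0.37) and that of KLK3 without doxycycline replicate 2 (-0.27). KDM1A (log2 -0.06 ± 0.07, adjusted p = 0.672) had no call. Of the 55 E2F-driven G1/S genes 24 rose (35 adjusted over the list alone). They included the helicase subunits MCM3 (log2 0.47 ± 0.06) and MCM4 (log2 0.50 ± 0.06), with a median of 0.32 (camera adjusted p = 3.4e-16, and 0.027 with an estimated correlation). The cyclin-dependent kinase CDK2 (log2 0.63 ± 0.08) and the CDK inhibitor CDKN1A (log2 0.75 ± 0.07) rose, and RBL2, a relative of RB1, fell (log2 -0.54 ± 0.07).

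Several other groups rose in C4-2 cells with doxycycline, with camera calls that were lost with an estimated correlation. ATF4 stress genes rose in 18 of 30 cases (20 adjusted over the list alone). Among them were the glutathione-degrading enzyme CHAC1 (log2 1.17 ± 0.12) and the serine synthesis enzyme PSAT1 (log2 0.58 ± 0.06; adjusted p = 0.0548 with an estimated correlation). In the DHT experiment edgeR called 0 ATF4 genes after 3 days of doxycycline (0 higher and 3 lower at an unadjusted p under 0.05). After 30 days it called 2 (3 higher and 6 lower unadjusted). CHAC1 stood there at -0.03 ± 0.10 and -0.05 ± 0.10. Its response differed between the 2 C4-2 tables by 1.21 ± 0.16 (adjusted p = 7.81e-05 in the joint edgeR fit). G2/M genes rose in 4 of 46 cases, with a median of 0.14 (adjusted p = 0.287 with an estimated correlation). Homologous recombination genes rose in 6 of 22 (8 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). Sterol genes rose in 7 of 25 cases (8 adjusted over the list alone), for example the sterol sensor INSIG1 (log2 0.57 ± 0.07; adjusted p = 0.159 with an estimated correlation). They went the other way with doxycycline in the DHT experiment. There 0 were higher and 6 lower after 3 days at an unadjusted p under 0.05 in edgeR. After 30 days 0 were higher and 9 lower, of which 3 were called. Replication-dependent histone genes rose in 7 of 28 cases (12 adjusted over the list alone, 2 called by DESeq2), with HIST1H2BJ at 1.28 ± 0.13 and HIST1H2BK at 0.97 ± 0.08 (adjusted p = 0.0548 with an estimated correlation). Reads shared within the histone family make these values uncertain. The kit of this table was for mRNA, unlike the total RNA kits of the DHT and LNCaP tables. Among 41 androgen-induced genes 7 rose and 7 fell (13 and 9 adjusted over the list alone; camera adjusted p = 0.353). The vesicle GTPase RAB3B (log2 0.42 ± 0.07) was among those that rose and the protease gene TMPRSS2 (log2 -0.46 ± 0.05) among those that fell. Of 18 members and partners of the LSD1-CoREST complex, MTA2 (log2 -0.62 ± 0.07) and ZMYM3 (log2 -0.41 ± 0.07) fell and the LSD1 relative KDM1B rose (log2 0.27 ± 0.08). ZMYM3 lost its call without DMSO replicate 1 (-0.37) or doxycycline replicate 2 (-0.39). KDM1B lost it without DMSO replicate 1 (0.24) or 2 (0.29) or doxycycline replicate 1 (0.30) or 2 (0.23) or combination replicate 1 (0.27) or 2 (0.27). Of the 13 protein genes of the mitochondrial genome 12 rose (13 adjusted over the list alone; median 0.59, adjusted p = 0.304 with an estimated correlation). The share of all counts on these 13 genes was 2.72% and 3.58% in the 2 DMSO libraries against 3.99% to 4.61% in the other 6 libraries of the table.

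**Figure D2:**
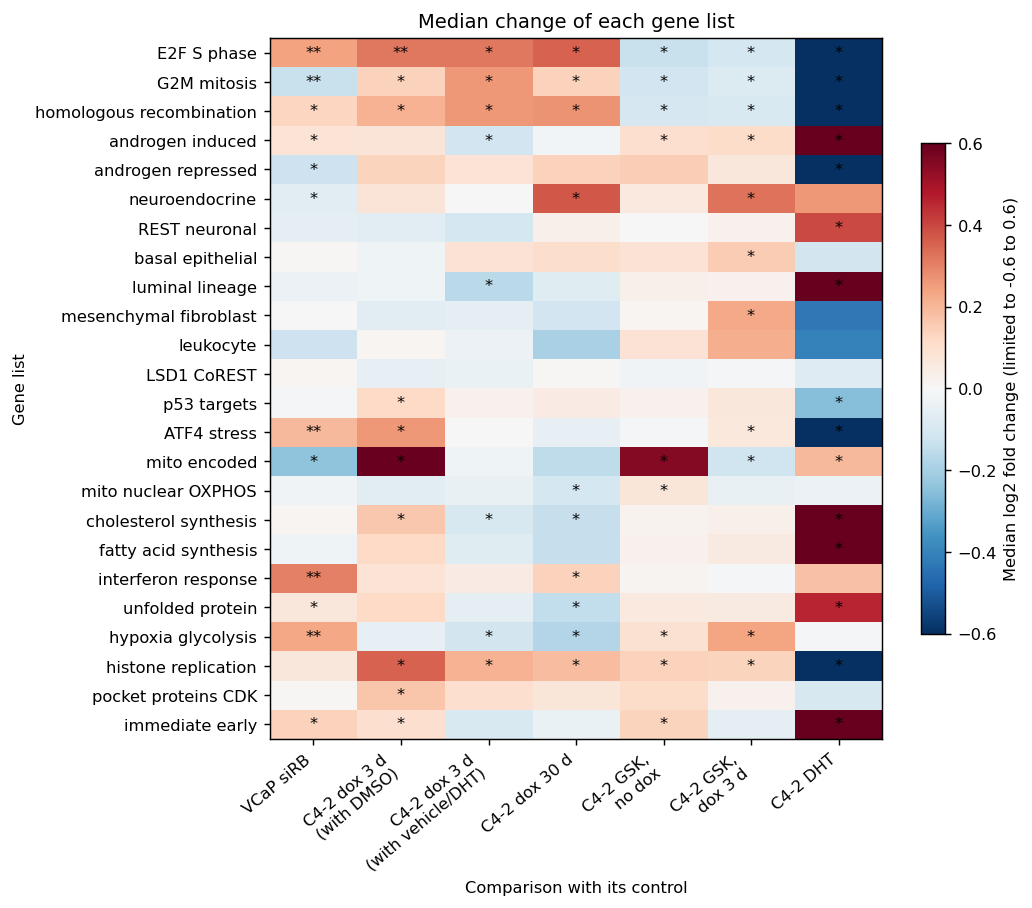
Median log2 fold change of each gene list (vertical) in each tested comparison (horizontal), with colour for the median; * marks camera adjusted p under 0.05 with the preset correlation and ** a list that also passed with an estimated correlation. The E2F list had medians of 0.24 in VCaP cells and 0.32 in C4-2 cells with doxycycline, and -0.66 with DHT.

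In all, 783 genes rose and 661 fell of 18423 tested in this comparison. The microRNA gene MIR30A rose most (log2 5.43 ± 0.12, adjusted p = 8.19e-15). Also among the largest rises were those of RP1-86C11.7 (log2 1.71 ± 0.24), the potassium channel KCNK13 (log2 1.46 ± 0.26), FEM1A (log2 1.43 ± 0.28) and RP5-1120P11.1 (log2 1.36 ± 0.19). After RB1, the pseudogene LAP3P2 (log2 -1.55 ± 0.28, uncertain because it shares sequence with LAP3), the cyclophilin PPIC (log2 -1.39 ± 0.15), the myosin light chain MYL9 (log2 -1.28 ± 0.25), GS1-358P8.4 (log2 -1.21 ± 0.11) and ornithine decarboxylase ODC1 (log2 -1.19 ± 0.06) fell most. DESeq2 called 640 genes up and 544 down. The count was 279 without DMSO replicate 1, 512 without DMSO replicate 2, and 323 and 351 without doxycycline replicate 1 and 2. It was 3200 and 3178 without GSK2879552 replicate 1 and 2, which enter the estimate of the spread. The call of FEM1A ended without DMSO replicate 2 (1.10) or doxycycline replicate 1 (1.27), that of MYL9 without DMSO replicate 1 (-1.14) or doxycycline replicate 1 (-1.24) and that of LAP3P2 without DMSO replicate 2 (-1.15).

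The DHT table gave a further view of RB1 knockdown in C4-2 cells, after 3 and 30 days of doxycycline, each averaged over vehicle and DHT (n = 2 libraries per level). RB1 stood at 48.1 CPM with vehicle and 51.1 CPM with DHT before doxycycline, at 7.82 and 10.0 CPM after 3 days and at 6.27 and 6.25 CPM after 30 days. It fell by 2.49 ± 0.11 at 3 days (edgeR adjusted p = 3.4e-15) and by 2.98 ± 0.11 at 30 days (adjusted p = 1.59e-16). At 3 days 47 genes rose and 34 fell of 17300 tested. E2F1 rose by 0.43 ± 0.08 (adjusted p = 0.0093). Of the 55 E2F-driven genes 17 rose (50 adjusted over the list alone, 10 called by DESeq2), including MCM3 (log2 0.43 ± 0.07) and WDR76 (log2 0.51 ± 0.08), with a median of 0.32 (camera adjusted p = 9.24e-24; adjusted p = 0.711 with an estimated correlation). None of the 46 G2/M genes passed edgeR's test over all genes, although 37 had an unadjusted p under 0.05 and 34 rose adjusted over the list alone (median 0.26; adjusted p = 0.711 with an estimated correlation). With DESeq2 the count was 0. These averages mix unlike values, as the median log2 ratio of DHT to vehicle changed with doxycycline. It was -1.04 for G2/M and -0.86 for E2F-driven genes before doxycycline, and -0.53 and -0.51 after 3 days (1 library each). The rise of these lists was thus larger between the DHT libraries than between the vehicle libraries, which was not tested for the lists. MIR30A (log2 5.76 ± 0.12), the apoptosis inhibitor BIRC3 (log2 0.70 ± 0.12), the replication checkpoint gene CLSPN (log2 0.58 ± 0.13), FAM111B (log2 0.52 ± 0.08) and WDR76 were among the genes that rose most. After RB1, the deubiquitinase STAMBP (log2 -0.89 ± 0.09), the CDK inhibitor CDKN1C (log2 -0.61 ± 0.14), the iron transporter SLC11A2 (log2 -0.61 ± 0.07), ATP6V1G1 (log2 -0.55 ± 0.07) and GPR180 (log2 -0.51 ± 0.09) fell most. KDM1A (log2 -0.05 ± 0.07, adjusted p = 0.882) and KLK3 (log2 -0.18 ± 0.07, adjusted p = 0.375) had no call. DESeq2 called 17 genes up and 13 down. edgeR called 1002 genes without the vehicle library, and 177 without the vehicle library of 3 days. The count was 232 and 229 without the vehicle and DHT libraries of 30 days, and 19 without the DHT library of 3 days. Without that last library the calls of E2F1 (0.27), MCM3 (0.33), WDR76 (0.41), BIRC3 (0.37), CLSPN (0.32), FAM111B (0.36), CDKN1C (-0.28) and GPR180 (-0.42) ended. So did those of BIRC3 (0.36), CLSPN (0.42) and CDKN1C (-0.40) without the DHT library before doxycycline, while KLK3 gained a call without the vehicle library (-0.30).

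After 30 days 434 genes rose and 263 fell of 17300 tested. E2F1 rose by 0.52 ± 0.08 (edgeR adjusted p = 0.000268). In all 41 of the 55 E2F-driven G1/S genes rose (50 adjusted over the list alone, 14 called by DESeq2; median 0.35). They included the primase PRIM1 (log2 0.67 ± 0.09) and the RB1 relative RBL1 (log2 0.62 ± 0.09; camera adjusted p = 1.41e-20; adjusted p = 0.72 with an estimated correlation). Homologous recombination genes rose in 7 of 22 cases (14 adjusted over the list alone, 2 called by DESeq2), such as the helicase BRIP1 (log2 0.59 ± 0.10) and BRCA1 (log2 0.49 ± 0.09; adjusted p = 0.72 with an estimated correlation). The cyclin-dependent kinase CDK6 rose (log2 0.76 ± 0.12) and the cyclin CCND1 fell (log2 -0.35 ± 0.06). Among 9 measured neuroendocrine markers PEG10 (log2 0.82 ± 0.08) and the synaptotagmin SYT4 (log2 0.71 ± 0.07) rose and UCHL1 fell (log2 -0.51 ± 0.12; adjusted p = 0.72 with an estimated correlation). The endoplasmic reticulum chaperone HSPA5 (log2 -0.39 ± 0.07) and the mitophagy gene BNIP3 (log2 -0.42 ± 0.07) fell. They belonged to the 4 of 26 genes of the unfolded protein response and the 4 of 23 of hypoxia that did (2 and 2 called by DESeq2; adjusted p = 0.72 and 0.72 with an estimated correlation). MIR30A (log2 5.66 ± 0.12), SLITRK6 (log2 1.36 ± 0.18), the collagen cross-linking enzyme LOX (log2 1.22 ± 0.16), CNTNAP2 (log2 1.22 ± 0.13) and ARNT2 (log2 1.17 ± 0.26) were among the genes that rose most. After RB1, the small heat shock protein HSPB8 (log2 -1.46 ± 0.31), the adducin ADD3 (log2 -1.33 ± 0.09), RP1-34B20.4 (log2 -1.30 ± 0.28), SLC22A31 (log2 -1.22 ± 0.25) and ANGPTL4 (log2 -1.06 ± 0.26) fell most. KLK3 fell (log2 -0.26 ± 0.07, adjusted p = 0.0364), while KDM1A (log2 0.02 ± 0.07, adjusted p = 0.945) had no call. DESeq2 called 104 genes up and 57 down, and edgeR called 1965 without the vehicle library, 424 without the DHT library and 207 without the DHT library of 30 days. Without that last library the calls of SLITRK6 (1.01), HSPB8 (-1.22), RP1-34B20.4 (-1.44), SLC22A31 (-0.97), CDK6 (0.57), CCND1 (-0.31) and UCHL1 (-0.32) ended. Those of SLITRK6 (0.81), HSPB8 (-1.32) and UCHL1 (-0.32) ended without the DHT library. ANGPTL4 lost its call without the vehicle library (-0.62) or that of 30 days (-0.90), ARNT2 without the latter (0.93). KLK3 lost it without the DHT library before doxycycline (-0.14), the vehicle (-0.26) or DHT (-0.26) library of 3 days, or the vehicle (-0.33) or DHT (-0.19) library of 30 days.

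Genes called after RB1 siRNA in VCaP cells and after doxycycline in C4-2-tet-shRB cells, which have no library in common, asked what the 2 lines share. Of 13289 genes tested in VCaP cells and in C4-2 cells with doxycycline in the table with GSK2879552, 78 rose in both, where independent lists would share 20.9 (Fisher's exact test, p = 6.76e-25). MCM4, SLC7A11, MCM2, MCM3 and WEE1, a kinase that delays mitosis, led these. Another 27 fell in both (15.6 by independence, Fisher's exact p = 0.00525), led by RB1, MPZL3, SLC4A4, EEF2 and RPL3, and 60 had opposite calls (36.0 by independence). Against 3 days of doxycycline in the DHT experiment 20 genes rose in both (1.38 by independence), led by MCM2, MCM3, MCM5, FEN1 and E2F1, and 3 fell in both (RB1, SLC36A1 and SLC30A4; 0.827 by independence), while 5 had opposite calls (2.15 by independence). Against 30 days 50 rose in both (11.7 by independence), led by MCM2, E2F1, PRIM1, MCM4 and MCM3, 14 fell in both (6.28 by independence) and 31 had opposite calls (17.4 by independence). Opposite calls exceeded independence in each pairing, so the excess of shared falls does not by itself show a shared direction. The shared falls also include RB1, the targeted gene. Across all genes the fold changes were nearly unrelated, with Pearson correlations of 0.0556, 0.0463 and 0.0395 (0.0537, 0.0525 and 0.0627 at a mean log2 CPM of at least 1); genes are not independent replicates.

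DHT against vehicle in C4-2 cells, averaged over the doxycycline levels, asked for the androgen response (n = 3 libraries each). Of 17300 genes 4206 rose and 3943 fell, 722 and 684 of them at least 2-fold. With median-of-ratios scaling 4241 rose and 3872 fell, while scaling by total counts was not run for this comparison. At 0, 3 and 30 days of doxycycline, TMM placed the 1-library DHT ratios 0.21, 0.18 and 0.16 log2 above scaling by total counts. The balance of rises and falls, and changes of about that size, may thus depend on the scaling. KLK3 rose by 1.03 ± 0.06 (edgeR adjusted p = 2.5e-14) and E2F1 fell (log2 -0.71 ± 0.07, adjusted p = 8.11e-10). KDM1A also fell (log2 -0.26 ± 0.05, adjusted p = 0.000319), while RB1 had no call (log2 0.13 ± 0.09, adjusted p = 0.245). Of 44 androgen-induced genes 43 rose, among them the glucocorticoid receptor chaperone FKBP5 (log2 3.32 ± 0.06) and the metalloreductase STEAP4 (7818 counts against 5), and TSC22D3 fell (log2 -0.35 ± 0.05). The list median was 1.69 (camera adjusted p = 1.17e-23; adjusted p = 0.411 with an estimated correlation). Androgen-repressed genes fell in 11 of 16 cases, such as CAMK2N1 (log2 -2.80 ± 0.10) and SYTL2 (log2 -2.13 ± 0.08). They rose in 3, such as UGT2B11 (log2 3.24 ± 0.14, uncertain because UGT2B genes are near-identical; adjusted p = 0.498 with an estimated correlation).

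Proliferation genes fell with DHT and lipid synthesis genes rose. Of the 55 E2F-driven G1/S genes 53 fell, including MCM10 (log2 -1.12 ± 0.07) and the replication licensing factor CDT1 (log2 -1.08 ± 0.07), with a median of -0.66 (adjusted p = 0.498 with an estimated correlation). G2/M genes fell in 45 of 46 cases, homologous recombination genes in 20 of 22 and histone genes in 29 of 35. Examples are the spindle checkpoint gene MAD2L1 (log2 -1.08 ± 0.07), BARD1 (log2 -1.17 ± 0.06) and HIST1H4C (log2 -1.28 ± 0.07; adjusted p = 0.581, 0.498 and 0.581 with an estimated correlation). ATF4 stress genes fell in 26 of 30 cases, such as the cystine transporter SLC7A11 (log2 -1.36 ± 0.05) and STC2 (log2 -1.52 ± 0.06; adjusted p = 0.411 with an estimated correlation). Sterol genes rose in 22 of 24 cases, with the synthase HMGCS1 at 2.15 ± 0.06. Fatty acid genes rose in 13 of 15, with the acyl-CoA synthetase ACSL3 at 2.90 ± 0.06 and the elongase ELOVL5 at 1.94 ± 0.06 (adjusted p = 0.45 and 0.45 with an estimated correlation). Genes of the unfolded protein response rose in 23 of 26 cases, such as the cochaperones DNAJB9 (log2 1.34 ± 0.07) and DNAJC3 (log2 0.92 ± 0.05; adjusted p = 0.498 with an estimated correlation). The luminal keratin KRT8 rose by 2.33 ± 0.06. Of 9 neuroendocrine markers 4 rose, including PEG10 (log2 1.98 ± 0.06) and UCHL1 (log2 1.61 ± 0.10), and 3 fell (DESeq2 called 3 and 1; camera adjusted p = 0.522).

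Among the largest rises with DHT were those of genes nearly silent with vehicle, whose intervals cover counting error only. STEAP4 had 7818 counts against 5, a ratio of 1899 with a 95% counting interval of 814 to 5851, and CTB-167B5.2 had 526 counts against 1, a ratio of 639 with an overlapping interval of 114 to 25284. NBL1 (1654 against 18), the amino acid transporter SLC38A4 (302 against 4), SLC26A3 (537 against 13) and the transcription factor SNAI2 (410 against 13) also rose. LPPR1 (9 counts against 169), the chemokine receptor ACKR3 (log2 -3.72 ± 0.10), SLC6A20 (log2 -3.68 ± 0.26), PRSS1 (log2 -3.49 ± 0.27), COLEC12 (log2 -3.44 ± 0.10) and the growth factor BMP7 (log2 -3.08 ± 0.18) fell most. DESeq2 called 3026 genes up and 2297 down.

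The DHT response was also described at each doxycycline level, where 1 library per group gives no replicate check and no test within a level. Among genes with at least 100 counts in the compared pair of libraries, 475 were at least 2-fold higher and 444 at least 2-fold lower with DHT before doxycycline, 410 and 210 after 3 days, and 399 and 220 after 30 days. Androgen-induced genes had medians of 1.72, 1.59 and 1.69 at 0, 3 and 30 days, each at percentile 100 of 10000 random lists matched on expression. KLK3 was higher by 1.20, 0.96 and 0.94 and FKBP5 by 3.38, 3.22 and 3.36. E2F-driven genes had medians of -0.86, -0.51 and -0.67, G2/M genes of -1.04, -0.53 and -0.50 and histone genes of -1.16, -0.76 and -0.64, all at percentile 0. The percentiles do not measure the spread between libraries. STEAP4 had 2535 counts against 0, 2583 against 3 and 2700 against 2. TMM scaling placed these ratios 0.21, 0.18 and 0.16 log2 above scaling by total counts. The share of at least 2-fold differences that were higher with DHT was 51.7%, 66.1% and 64.5% with TMM and 30.4%, 44.3% and 44.3% with total counts. A test chosen after these values were seen asked whether the DHT response differed with doxycycline, with 3 and 30 days taken as replicates and 1 library per group without doxycycline. It called 9 of 17300 genes, 8 higher and 1 lower (1133 at an unadjusted p under 0.05 against 865 by chance; DESeq2 called 4). Proliferation genes were among them, as CENPF (log2 0.79 ± 0.12, adjusted p = 0.0124), ASPM (log2 0.90 ± 0.13), TOP2A (log2 0.70 ± 0.10) and MKI67 (log2 0.78 ± 0.14, adjusted p = 0.0421) stood less low with DHT after doxycycline. KLK3 (log2 -0.25 ± 0.10, adjusted p = 0.703) and E2F1 (log2 0.20 ± 0.14, adjusted p = 0.851) had no call. With the doxycycline levels kept, 1 residual degree of freedom was left and 242 genes were called. The response without doxycycline rests on 1 library each, so these calls do not separate RB1 loss from a deviation of those 2 libraries.

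**Figure D3:**
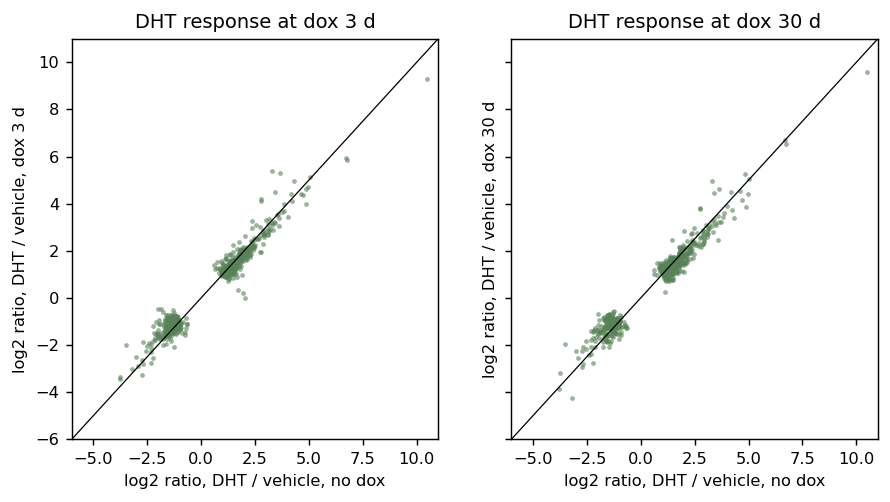
Log2 ratio of DHT to vehicle before doxycycline (horizontal) against the ratio after 3 and 30 days of doxycycline (vertical), with 1 point for each gene called and changed at least 2-fold with DHT in the additive model and with at least 100 counts at each level, and a line of equality. The 391 of these that rose had median ratios of 1.51, 1.46 and 1.43 at 0, 3 and 30 days, and the 224 that fell had -1.37, -1.18 and -1.16.

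GSK2879552 at 10 µM for 24 h asked what LSD1 inhibition does to C4-2 cells before RB1 knockdown (n = 2 per group). Of 18423 genes 114 rose and 11 fell, 30 and 1 of them at least 2-fold. The epithelial-mesenchymal transcription factor ZEB1 went from 1 count in both DMSO libraries together to 142 with the inhibitor, a ratio of 114 with a 95% counting interval of 20.1 to 4526 (edgeR adjusted p = 1.52e-05). AHNAK2 (log2 2.09 ± 0.14), the axon growth gene FEZ1 (log2 2.03 ± 0.18), the sodium channel subunit SCN4B (log2 1.88 ± 0.16), NAP1L3 (log2 1.87 ± 0.22) and LIX1L (log2 1.84 ± 0.10, adjusted p = 1.67e-08) followed. Among listed genes, the interferon-stimulated IFI6 (log2 1.01 ± 0.12), the intermediate filament VIM (log2 0.60 ± 0.10) and ELOVL5 (log2 0.65 ± 0.09) rose. VIM lost its call without DMSO replicate 1 (0.60) or 2 (0.60). RB1 (log2 0.16 ± 0.15, adjusted p = 0.716), KDM1A (log2 0.02 ± 0.07, adjusted p = 0.926), KLK3 (log2 0.11 ± 0.05, adjusted p = 0.405) and E2F1 (log2 -0.13 ± 0.08, adjusted p = 0.529) had no call. RB1 stood at 32.7 and 22.1 CPM with the inhibitor and gained a call without GSK2879552 replicate 2 (0.39).

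**Figure D4:**
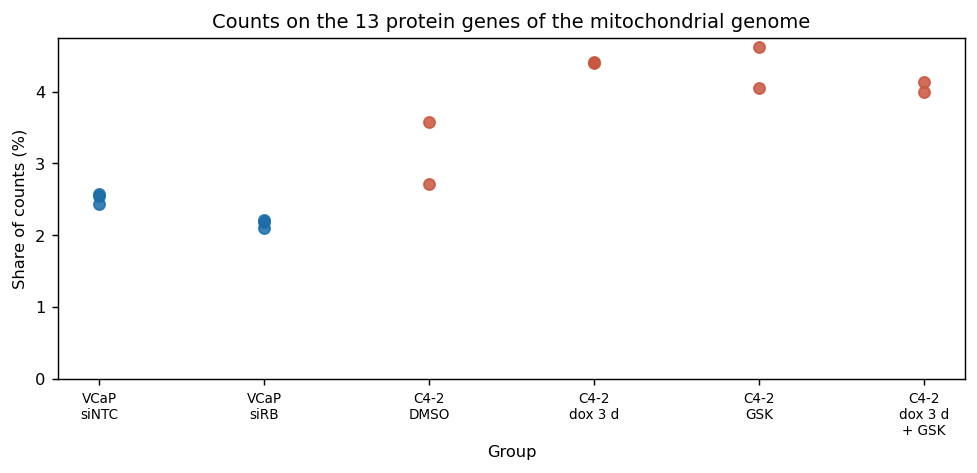
Share of counted reads on the 13 protein genes of the mitochondrial genome (%) in each library of the VCaP table and of the C4-2 GSK2879552 table, by group; each point is 1 library. The 2 DMSO libraries of the C4-2 table, at 2.72% and 3.58%, lie below the other 6 at 3.99% to 4.61%.

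Among the gene lists of this comparison, none of the 55 E2F-driven genes passed edgeR's test over all genes, 20 had an unadjusted p under 0.05, 14 fell adjusted over the list alone and DESeq2 called 1. The E2F median was -0.13 (camera adjusted p = 3.26e-07; adjusted p = 0.133 with an estimated correlation). MKI67, a proliferation marker, was the 1 of 46 G2/M genes that fell (5 adjusted over the list alone; log2 -0.31 ± 0.06; adjusted p = 0.307 with an estimated correlation). Androgen-induced genes rose in 2 of 41 cases (8 up and 1 down adjusted over the list alone; adjusted p = 0.243 with an estimated correlation). Protein genes of the mitochondrial genome rose in 12 of 13 cases (4 called by DESeq2; median 0.55; adjusted p = 0.307 with an estimated correlation), relative to the same 2 DMSO libraries whose share of counts on these 13 genes was 2.72% and 3.58%. DESeq2 called 110 genes up and 16 down, whereas edgeR called 41 and 69 without DMSO replicate 1 and 2, and 541 and 1735 without GSK2879552 replicate 1 and 2. BTBD19 (log2 -1.39 ± 0.30), ZNF460 (log2 -0.91 ± 0.18), ACTRT3 (log2 -0.90 ± 0.13), RP11-362K14.5 (log2 -0.89 ± 0.19), TNK2-AS1 (log2 -0.67 ± 0.14) and MYNN (log2 -0.56 ± 0.08) fell most. BTBD19 lost its call without DMSO replicate 1 (-1.61) or 2 (-1.12) or combination replicate 1 (-1.39). ZNF460 lost it without DMSO replicate 1 (-0.82) or 2 (-0.99). The RP11-362K14.5 call ended without DMSO replicate 1 (-0.95) or 2 (-0.82) or combination replicate 1 (-0.88) and that of MYNN without DMSO replicate 1 (-0.54). TNK2-AS1 lost its call without DMSO replicate 1 (-0.56) or 2 (-0.78) or doxycycline replicate 1 (-0.67) or 2 (-0.67) or combination replicate 1 (-0.67) or 2 (-0.67). MKI67 lost it without DMSO replicate 1 (-0.27) or 2 (-0.35) or doxycycline replicate 1 (-0.31) or 2 (-0.31) or combination replicate 1 (-0.31).

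The same inhibitor given after RB1 knockdown addressed the setting of the series title, LSD1 inhibition in RB1-depleted cells (n = 2 per group). It raised 229 genes and lowered 17 of 18423, 54 and 2 of them at least 2-fold. RB1 stood at 4.64 and 6.24 CPM with doxycycline alone and at 5.84 and 6.74 CPM with doxycycline and the inhibitor (log2 0.20 ± 0.21, adjusted p = 0.815). ZEB1 went from 5 to 164 counts, a ratio of 39.6 with a 95% counting interval of 16.6 to 124 (edgeR adjusted p = 1.89e-06). AHNAK2 (log2 2.64 ± 0.13, adjusted p = 3.17e-09), FEZ1 (log2 2.56 ± 0.18), SCN4B (log2 2.33 ± 0.16), LIX1L (log2 2.12 ± 0.10) and MAP3K15 (log2 2.00 ± 0.19) followed. Hypoxia and glycolysis genes rose in 11 of 22 cases (16 adjusted over the list alone). They were led by the glycolytic regulators PFKFB4 (log2 0.76 ± 0.07) and PFKFB3 (log2 0.59 ± 0.07; median 0.24; camera adjusted p = 1.09e-14; adjusted p = 0.0758 with an estimated correlation). The immediate early gene FOS (log2 1.11 ± 0.15), IFI6 (log2 1.09 ± 0.12), VIM (log2 0.74 ± 0.10) and the stress-induced STC2 (log2 0.51 ± 0.06) rose. Of 41 androgen-induced genes 6 rose (10 up and 1 down adjusted over the list alone), including NDRG1 (log2 0.36 ± 0.06; adjusted p = 0.0758 with an estimated correlation). NDRG1 lost its call without doxycycline replicate 1 (0.36) or 2 (0.34) or combination replicate 1 (0.33).

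BTBD19 (log2 -1.06 ± 0.24), RNA5-8SP6 (log2 -0.81 ± 0.14, a ribosomal RNA pseudogene and so uncertain), RP11-362K14.5 (log2 -0.78 ± 0.16), ACTRT3 (log2 -0.77 ± 0.12), MIR663A (log2 -0.69 ± 0.16, ribosomal-RNA-like and also uncertain) and CCDC85B (log2 -0.63 ± 0.14) fell most with the inhibitor after knockdown. None of the 55 E2F-driven genes passed edgeR's test (12 had an unadjusted p under 0.05, 11 of them lower; DESeq2 called 0), with a median of -0.11 (camera adjusted p = 4.12e-06; adjusted p = 0.0758 with an estimated correlation). E2F1 (log2 -0.23 ± 0.08, adjusted p = 0.226), KLK3 (log2 0.17 ± 0.05, adjusted p = 0.159) and KDM1A (log2 -0.02 ± 0.07, adjusted p = 0.951) had no call. E2F1 gained one without GSK2879552 replicate 1 (-0.23) or 2 (-0.24), as did KLK3 (0.16 and 0.16). DESeq2 called 175 genes up and 10 down. edgeR called 162 without DMSO replicate 2, and 83 and 78 without doxycycline replicate 1 and 2. It called 947 and 941 without GSK2879552 replicate 1 and 2, and 90 without either library of doxycycline with the inhibitor. BTBD19 lost its call without DMSO replicate 2 (-1.07) or doxycycline replicate 1 (-0.97) or 2 (-1.16) or combination replicate 1 (-1.22) or 2 (-0.95). RNA5-8SP6 lost it without doxycycline replicate 1 (-0.77) or combination replicate 1 (-0.89) or 2 (-0.76). RP11-362K14.5 lost it without doxycycline replicate 2 (-0.66) or combination replicate 1 (-0.87) or 2 (-0.71). MIR663A lost its call without DMSO replicate 1 (-0.70) or 2 (-0.70) or doxycycline replicate 1 (-0.65) or 2 (-0.76) or combination replicate 1 (-0.74) or 2 (-0.67). CCDC85B lost it without DMSO replicate 1 (-0.64) or 2 (-0.64) or doxycycline replicate 1 (-0.57) or 2 (-0.71) or combination replicate 1 (-0.57) or 2 (-0.70).

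**Figure D5:**
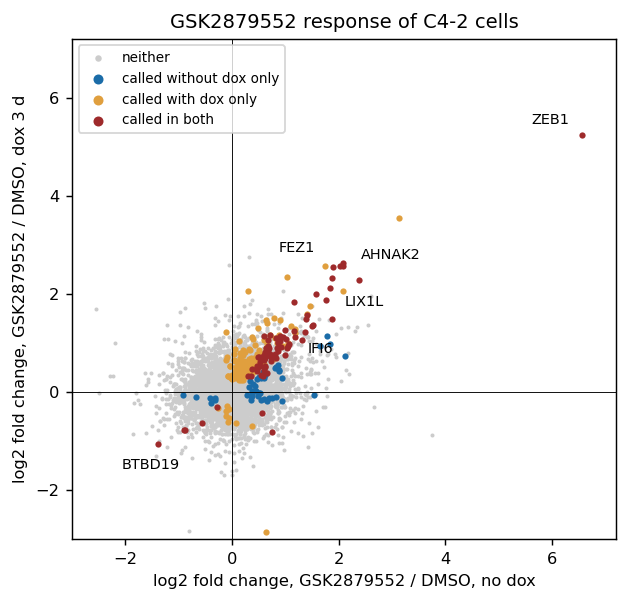
Log2 fold change with GSK2879552 without doxycycline (horizontal) against that with doxycycline (vertical) in C4-2 cells, 1 point per gene, with genes called in both comparisons marked. The 77 genes called in the same direction in both include ZEB1, AHNAK2, FEZ1, SCN4B and LIX1L in the upper right.

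The 2 responses to GSK2879552, which share no library, had 72 risen genes in common (1.42 by independence, Fisher's exact p = 5.36e-112), led by LIX1L, AHNAK2, SCN4B, FEZ1 and the syntaxin STX2. They also had 5 fallen genes in common (0.0102 by independence), MYNN, ACTRT3, IGF2R, RP11-362K14.5 and BTBD19, while 2 had opposite calls. Across all 18423 genes the Pearson correlation was 0.297, and 0.502 over the 14358 with a mean log2 CPM of at least 1. The direct test of whether the response differed with RB1 knockdown called 3 genes lower and none higher with edgeR (879 at an unadjusted p under 0.05; DESeq2 called 2 and 2). These were RNA5-8SP6 (log2 -1.56 ± 0.19, adjusted p = 0.00456), CTD-2328D6.1 (log2 -0.995 ± 0.13, adjusted p = 0.00456) and MT-ND4L (log2 -0.92 ± 0.14, adjusted p = 0.039, which overlaps MT-ND4 and is uncertain). RNA5-8SP6 and CTD-2328D6.1 are ribosomal-RNA-like and uncertain, so each call was ribosomal-RNA-like or mitochondrial. Together with MIR663A they made up 0.0099% and 0.0117% of counts in the DMSO libraries and 0.0148% and 0.0171% with the inhibitor. Their share was 0.0156% and 0.0148% with doxycycline and 0.0113% and 0.0106% with both. Hypoxia and glycolysis genes had a median difference of 0.21 (9 higher adjusted over the list alone; camera adjusted p = 6.03e-08; adjusted p = 0.255 with an estimated correlation), with PFKFB4 at 0.56 ± 0.09 (adjusted p = 0.0737). The interaction values of RB1 (log2 0.03 ± 0.26), KDM1A (log2 -0.04 ± 0.10), KLK3 (log2 0.06 ± 0.07) and E2F1 (log2 -0.09 ± 0.11) had no call. The count was 15 without DMSO replicate 2, 195 and 76 without GSK2879552 replicate 1 and 2, and 0 without replicate 2 of doxycycline with the inhibitor. RNA5-8SP6 lost its call without DMSO replicate 1 (-1.47) or combination replicate 2 (-1.50). CTD-2328D6.1 lost it without DMSO replicate 1 (-0.88) or combination replicate 2 (-0.95). MT-ND4L lost it without doxycycline replicate 1 (-0.94) or 2 (-0.92) or combination replicate 1 (-0.89) or 2 (-0.97).

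GSK2879552 at 1 µM for 2 days in LNCaP cells was described from 1 library per group, with no replicate check, and the 95% intervals cover counting error only. Of 11955 genes with at least 100 counts, 173 were at least 2-fold higher and 162 at least 2-fold lower. CD55, a complement inhibitor, was the highest of these at 9.79-fold (158 against 17 counts, interval 5.93 to 17.2), ahead of the deiodinase DIO3 (7.52-fold), KIAA1199 (7.53-fold), TENM1 (5.66-fold), FEZ1 (5.68-fold) and RP11-488L18.1 (4.87-fold). Of the 114 genes that rose with the inhibitor in C4-2 cells 85 were measured here and 61 were higher, and of the 229 that rose after doxycycline 134 of 172 were, against 48.6% of all 11829 genes in common. Of those that fell, 4 of 7 and 11 of 13 were lower. Higher ones included AHNAK2 at 4.53-fold (interval 3.9 to 5.28), LIX1L at 2.49-fold, VIM at 2.09-fold and IFI6 at 2.06-fold. Below the minimum of counts, SCN4B had 45 against 6 (interval 3.36 to 22.7) and ZEB1 had 29 counts against 0, at least 10.2-fold higher against a floor of 3 counts. The immediate early genes FOS (5 against 502 counts, ratio 0.0105, opposite to its rise with the inhibitor in C4-2 cells after doxycycline) and EGR1 (9 against 646, ratio 0.0147) were lowest, with RP11-54O7.17 (ratio 0.0615), RP1-276N6.2 (ratio 0.149) and the uncertain ribosomal RNA pseudogenes RNA5-8SP3 (ratio 0.0963) and RNA5-8SP6 (ratio 0.161).

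Proliferation genes stood lower in the LNCaP library with the inhibitor. The list medians were -0.68 for E2F-driven genes, -0.66 for G2/M genes and -0.74 for histone genes, each at percentile 0 of 10000 random lists. Genes of a list may move together between any 2 libraries, so these percentiles do not tie the shifts to the inhibitor. E2F1 was at a ratio of 0.438 (interval 0.36 to 0.531), the DNA methylation cofactor UHRF1 at 0.214 and ribonucleotide reductase RRM2 at 0.275. KLK3 was at a ratio of 0.479 (3585 against 7881 counts, interval 0.461 to 0.499), KLK2 at 0.506 and TMPRSS2 at 0.729, and the androgen-induced list had a median of -0.20 (percentile 1.52). KDM1A was at 1.05 and RB1 at 1.25 (437 against 367 counts). ATF4 stress genes had a median of 0.50 (percentile 100), with SLC7A11 3.15-fold and the stress transcription factor DDIT3 2.81-fold higher, and p53 target genes had 0.21 (percentile 99.5). Hypoxia and glycolysis genes, of which 11 of 22 rose with the inhibitor in C4-2 cells after doxycycline (adjusted p = 0.0758 with an estimated correlation) and none without it (median 0.09; 7 adjusted over the list alone, 3 called by DESeq2), had -0.26 here (percentile 1.1). Sterol genes stood at -0.38 and protein genes of the mitochondrial genome at -0.83, both at percentile 0. The latter made up 0.336% of counts with vehicle and 0.220% with the inhibitor. The mitochondrial ribosomal RNA MT-RNR2 made up 14.9% and 16.1%, so the RNA composition of the 2 libraries differed as well.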

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

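The joint fit of both C4-2 tables and every test of an explanation in this part were chosen after the results were seen. The test of whether the response to GSK2879552 differed with doxycycline, planned earlier, gave a difference for CTD-2328D6.1 (log2 -0.995 ± 0.13), RNA5-8SP6 (log2 -1.56 ± 0.19) and MT-ND4L (log2 -0.92 ± 0.14), all of them uncertain. Among the lists, it gave median differences of -0.71 for genes of the mitochondrial genome, -0.10 for nuclear genes of oxidative phosphorylation, 0.21 for hypoxia genes and -0.22 for immediate early genes. The adjusted p of these lists was 0.496, 0.253, 0.255 and 0.496 with an estimated correlation. G2/M genes had a median change of -0.14 with RB1 siRNA in VCaP cells and 0.14 with doxycycline in C4-2 cells (adjusted p = 0.0433 and 0.287 with an estimated correlation), with the list on opposite sides in every library of the 2 lines. This difference was not tested. Genes of the mitochondrial genome, also untested, were at -0.24 in VCaP cells and 0.59 in C4-2 cells (adjusted p = 0.0711 and 0.304 with an estimated correlation). In the C4-2 table with DHT they were at -0.02 after 3 days and -0.15 after 30 days of doxycycline.

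Genes of the mitochondrial genome stood low in the 2 DMSO libraries of the C4-2 table with GSK2879552, which are the reference of both the doxycycline and the inhibitor effect. If the effects of doxycycline and the inhibitor add, a rise caused by doxycycline itself would show with the inhibitor present too. There the median change of the 13 genes was -0.11 (median of the SEs of the genes 0.10). The libraries with the inhibitor alone already stood at 4.61% and 4.05%, so a doxycycline effect that does not add to that of the inhibitor is not excluded. A rise caused by RB1 depletion in both lines is argued against by the VCaP median of -0.24 (median of the SEs of the genes 0.03). A lower yield in the 2 DMSO libraries stays open: their shares differed by a ratio of 1.32, against 1.00, 1.04 and 1.14 in the other groups, which may point to handling but cannot be told apart from a state of the untreated cultures with 2 libraries.

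The response to doxycycline differed between the 2 C4-2 tables for 207 of 19898 genes (134 higher and 73 lower in the table with GSK2879552; 2213 at an unadjusted p under 0.05; 230 with DESeq2). The differences were -1.43 ± 0.16 for GS1-358P8.4 (adjusted p = 3.34e-06 in edgeR), -1.42 ± 0.20 for PPIC, -1.17 ± 0.10 for ODC1 and -1.17 ± 0.12 for the aminopeptidase LAP3, whereas STAMBP had 0.91 ± 0.12 and RB1 0.32 ± 0.23 (adjusted p = 0.656). Upward, the largest at a mean log2 CPM of at least 1 were FEM1A (1.96 ± 0.44), RP5-1120P11.1 (1.48 ± 0.27) and AC104135.4 (1.44 ± 0.31). FEM1A and RP5-1120P11.1 were among the rises with doxycycline given above.

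Of 22 genes other than RB1 that fell at least 2-fold with doxycycline in the table with GSK2879552, 17 were measured in that with DHT. If RB1 loss or doxycycline alone lowered them, they would fall in both tables, but their median at 3 days was -0.0137 (SE 0.115) against -1.21 in the former table. A difference in knockdown construct, medium or library kit could give such a split and stays open with the 207 genes above, since these differ together between the tables and cannot be told apart.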

How the results depend on the processing

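The crossed replicate numbers, the thinned VCaP libraries, the removal of genes of the mitochondrial genome and the test of the DHT response with and without doxycycline were chosen after seeing the data. That test called 9 genes, against 4 with DESeq2, 242 with the doxycycline levels kept (10 with DESeq2) and 54 to 135 without 1 of the 4 libraries with doxycycline. With median-of-ratios scaling all 8 counts of called genes stayed within 1.5 times, as did the VCaP count thinned to the shallowest library (690 against 790) and the 4 counts of the C4-2 table without genes of the mitochondrial genome. DESeq2 called 341 genes in VCaP cells (790 in edgeR), 5323 with DHT (8149), 30 at 3 days (81) and 161 at 30 days of doxycycline (697). Without a count filter edgeR called 330 genes with GSK2879552 (125), 406 with the inhibitor after doxycycline (246), 39 for the difference between these (3) and 222 at 3 days of doxycycline (81). A fit of the compared groups alone called 3540 genes for doxycycline (1444) and 1173 for the inhibitor after doxycycline (246). Replicate numbers as a block gave 908 and 161 genes for these 2 comparisons and 973 in VCaP cells. Whether the numbers pair the samples was left open. Residual correlations between libraries of the same number were -0.125 to 0.0353 over 6 pairs of groups in C4-2 cells, negative in the 3 with the GSK2879552 group (-0.0849, -0.0987 and -0.125), and 0.0103 to 0.0284 in VCaP cells. With crossed numbers in the GSK2879552 group the block gave 3051, 727, 805 and 48 genes for doxycycline, the inhibitor, the inhibitor after doxycycline and the difference. Lanes taken as replicates gave 2282 genes at 3 days, 3705 at 30 days and 6675 in LNCaP cells (335 by the 2-fold rule). A minimum of 30 counts gave 723 genes in LNCaP cells and 1435, 1036 and 999 with DHT at 0, 3 and 30 days (919, 620 and 619), and a minimum of 300 gave 163 in LNCaP cells. Lane counts hold no spread between cultures; for the other changes the cause was not tested.

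With 1 library left out, the counts ranged from 515 to 826 in VCaP cells, 279 to 3200 for doxycycline, 41 to 1735 for the inhibitor, 78 to 947 for the inhibitor after doxycycline and 0 to 195 for the difference. They ranged from 6672 to 7595 for DHT, 19 to 1002 at 3 days and 207 to 1965 at 30 days of doxycycline. The lowest came without control siRNA replicate 3, DMSO replicate 1, DMSO replicate 1, doxycycline replicate 2, replicate 2 of the combination (879 genes at an unadjusted p under 0.05 with all libraries), and, with DHT, the DHT library of 3 days (for DHT and 3 days) and of 30 days. A lone library left in a group was assumed to vary like the others, and the cause of these moves was not tested. In the C4-2 table with GSK2879552, the pair given the inhibitor alone differed most (chi-square ratio 7.88, against 1.61 to 3.56 in the other groups). This pair enters the shared estimate of the spread. Leaving out either of its libraries raised the count in each comparison of that table. Of 79 camera calls 6 passed with an estimated correlation, namely 5 in VCaP cells and 1 for doxycycline in C4-2 cells. In the DHT table this check had 2 residual degrees of freedom and thus little power. The lowest camera adjusted p of any list there was 0.411 for DHT, 0.711 at 3 days and 0.72 at 30 days. A call lost in that table therefore does not show that the list was unchanged. Over 4395 alternatives of named genes, 3866 kept direction and side of the threshold, 516 lost the call and 13 gained it. Of 79 lists with at least 3 edgeR calls, DESeq2 called fewer genes in 59, by more than 1.5 times in 29. Under scaling by total counts 42 of 92 list medians without a test moved, and 6 of 92 changed sign (the largest at 0.17 in the main analysis). The share of at least 2-fold differences that were higher with DHT fell from 51.7%, 66.1% and 64.5% to 30.4%, 44.3% and 44.3% at 0, 3 and 30 days, so that the majority turned from higher to lower. Overlaps of called genes restricted to a mean log2 CPM of at least 1 stayed within 1.5 times (103, 23, 64 and 74 genes against 105, 23, 64 and 77). The 10 possible splits of 3 against 3 libraries are too few for a share under 0.05: in VCaP cells the real split gave 790 genes and the highest other 0, and with DHT 8149 and 0, so that 1 of 10 splits reached the real count in each.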

Other observations

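The comparison of doxycycline in the presence of GSK2879552 and the tests of the hypothesis on MIR30A were chosen after the results were seen. Doxycycline in the presence of GSK2879552 compared the combination with the inhibitor alone in C4-2 cells (2 libraries each) and called 832 genes higher and 590 lower of 18423. RB1 fell by 2.14 ± 0.18 (adjusted p = 2.53e-06 in edgeR), and E2F1 (log2 0.33 ± 0.08, adjusted p = 0.0177) and MCM2 (log2 0.45 ± 0.06, adjusted p = 0.000335) rose. Ornithine decarboxylase ODC1 (log2 -1.003 ± 0.06), the aminopeptidase LAP3 (log2 -1.20 ± 0.09), PPIC (log2 -1.56 ± 0.15) and the nuclear lamin LMNB1 (log2 -0.83 ± 0.07) fell, and STAMBP had no call (log2 0.01 ± 0.08, adjusted p = 0.964).

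Further lists moved with DHT in C4-2 cells. Immediate early genes rose in 10 of 14 cases and fell in 3, among them the phosphatase DUSP1 (log2 1.44 ± 0.07) and the nuclear receptor NR4A1 (log2 1.12 ± 0.08) upward and MYC (log2 -0.92 ± 0.05) downward (adjusted p = 0.411 with an estimated correlation). Of 26 p53 target genes 16 fell and 5 rose, the latter including GDF15 (log2 1.41 ± 0.05) and CDKN1A (log2 0.66 ± 0.06; adjusted p = 0.498 with an estimated correlation). Luminal lineage genes rose in 11 of 16 cases, such as the racemase AMACR (log2 2.07 ± 0.07), and fell in 2, such as the transcription factor GATA2 (log2 -0.70 ± 0.06; adjusted p = 0.411 with an estimated correlation).

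MIR30A rose with doxycycline in each C4-2 comparison, and one hypothesis is that the counted reads come from the induced knockdown construct. A rise of the MIR30A host gene is argued against as the whole source, since LINC00472 changed by 1.09 (SE 0.45) at 3 days where MIR30A rose by 5.76. Reads from the construct may account for the rise, whose smallest value was 5.43 for MIR30A, but this cannot be told apart from a true induction, because the sequence of the construct was not given in the sources used here.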
